A study of Homo sapiens with 18 samples.

How the data were processed

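MCF10A cells, an established non-malignant breast epithelial line, were profiled by poly-A RNA sequencing in 2D and 3D culture on compliant gels at 3 timepoints, with 3 libraries in each of the 6 groups. Groups and replicate numbers were taken from the sample titles, and 0 sample columns of the files were left unused. Each replicate number carries a date shared by all groups, so the numbers pair libraries across groups. The labels do not say what else the libraries of one number have in common or whether they come from separate cultures, and the p-values measure the spread between these samples.

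Per the labels, reads were handled with STAR 2.7.1a, HOMER, edgeR and limma on hg38, with no role or order stated; the annotation release, the strand used in counting and the filters are not given in the sources used here. The deposited count table holds whole numbers for 60662 genes in 18 libraries with no normalisation by the authors. Its sums were 4.73 to 5.73 times the library totals per the file headers. The median count rose from 28 for genes with 1 transcript to 3564 for genes with at least 17 (rank correlation 0.55), as when a read is counted once for each transcript. How reads were counted is not stated, so this stays an inference. The sums exceed the header totals and are not read as depth, CPM is not treated as comparable between genes, and no counting intervals are given. At timepoint 2 the ratio of sums to header totals was 5.54 to 5.73 in 3D and 4.96 to 5.26 in 2D. The deposited log2 CPM table holds 13677 genes in 17 libraries, scaled by the authors. Within each library it correlated with the log2 of the deposited counts at 0.9996 or more, which does not test the scaling between libraries. The deposited tables for each timepoint give the authors' log2 fold changes, 3D minus 2D, and the p-values and adjusted p-values of a limma fit per the file headers.

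All tests used the deposited counts. The library of 2D timepoint 3 replicate 1 was left out of the tests because its labels list the raw table alone, and 17 of 18 libraries were fitted. Genes were kept by edgeR's filterByExpr, which left 18592, and matched to current symbols where one existed, as for 60306 genes of the table. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The comparisons were 3D against 2D at each timepoint and on average, the later timepoints against timepoint 1 within each culture, and the interactions of culture and time. The common dispersion was 0.0686, and 0.0363 with the replicate number as a block. The groups, comparisons, alternatives other than those said below to be added later, and the rule for naming genes were chosen before the data were examined. CPM values are group means with SD.

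Genes were named by a rule. For each culture comparison up to 8 higher and 8 lower genes with the largest log2 fold change were taken among those that passed, did not overlap in CPM between groups and had a mean count of at least 50. For the average, the 3 timepoint differences had to have one sign. For time comparisons and interactions up to 5 each were taken. In each described list up to 4 members with the smallest p were taken, and 18 genes of the unfolded protein response, filamins, actomyosin, YAP and sterol synthesis were taken in every culture comparison. Genes named outside the rule are said to be. A gene that the rule would name is left out of the text because it is withheld for evaluation.

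Gene lists, 43 with 982 genes of which 916 were measured, were written from general knowledge and tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and again with an estimated correlation. Members were counted as called over all genes and when adjusted over the list alone. Lists that share members are not independent.

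Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no filter and a stricter one, all 18 libraries, the replicate block, the groups compared alone, a fold of at least 2, and leaving out each library. For the lists they also included fry. Counts divided by the number of transcripts, an offset for gene length and GC content, and the block with an estimated correlation for the lists were added after the data were seen. Length and GC content were known for 18398 of the tested genes.

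The tests were tested on simulated data. Folds of 1.5, 2 and 4 were recovered for 0%, 35.8% and 86.4% of changed genes at timepoint 2 with 2 false calls, and for 11.9%, 61.2% and 95.5% with the replicate block with 6 false calls; no direction was wrong. At timepoint 1 the percentages were 0, 11.9 and 89.4, and 16.4, 53.7 and 95.5 with the block. At timepoint 3 they were 1.49, 11.9 and 84.8, and 10.4, 41.8 and 89.4 with the block. Most changes of 1.5 times were missed in either fit. A simulated list of 30 shifted genes was found by camera at timepoint 2 (p = 1.1e-14) and with an estimated correlation (p = 2.7e-06), and an unshifted one was not (p = 0.17). At the preset correlation the unshifted list had p = 0.056 at timepoint 1, 0.049 with the block, and 0.96 at timepoint 3. Simulated genes varied independently around their fitted means, and list members were drawn at random. The simulation therefore does not test the preset correlation for lists whose genes vary together.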

Results

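RNA was sequenced from MCF10A cells, an immortalised but non-malignant human breast epithelial line, kept on compliant polyacrylamide gels that carried Matrigel, a laminin-rich basement membrane extract. The cells received either fresh medium alone (2D) or medium with 2% Matrigel, which surrounds them with matrix (3D), and were collected at 3 timepoints. The protocol in the labels lists harvests at 3, 12 and 21 h, and timepoints 1, 2 and 3 are matched to these hours only by their order. Each of the 6 groups had 3 libraries. The tests used 17 of the 18, because the library labelled 2D timepoint 3 replicate 1 was listed by its labels with the raw counts alone, so the 2D group of timepoint 3 had n = 2. Library totals in the deposited file headers ran from 9.31 M to 17.7 M. The summed gene counts ran from 49.8 M to 93.9 M and were 4.73 to 5.73 times those totals. Between 22632 and 24584 genes had at least 1 count in a library.

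The first principal component of log2 CPM held 26.8% of the variance over the 18 libraries and separated timepoint 1, where 2D and 3D libraries lay together, from the later 3D libraries. The 2D libraries of timepoints 2 and 3 lay between them. Libraries with one replicate number carry one date in the labels, and they deviated from their group means together, with a mean correlation across genes of 0.32 within a timepoint. Counts from a fit with the replicate number as a block therefore stand beside the main ones.

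**Figure D1:**
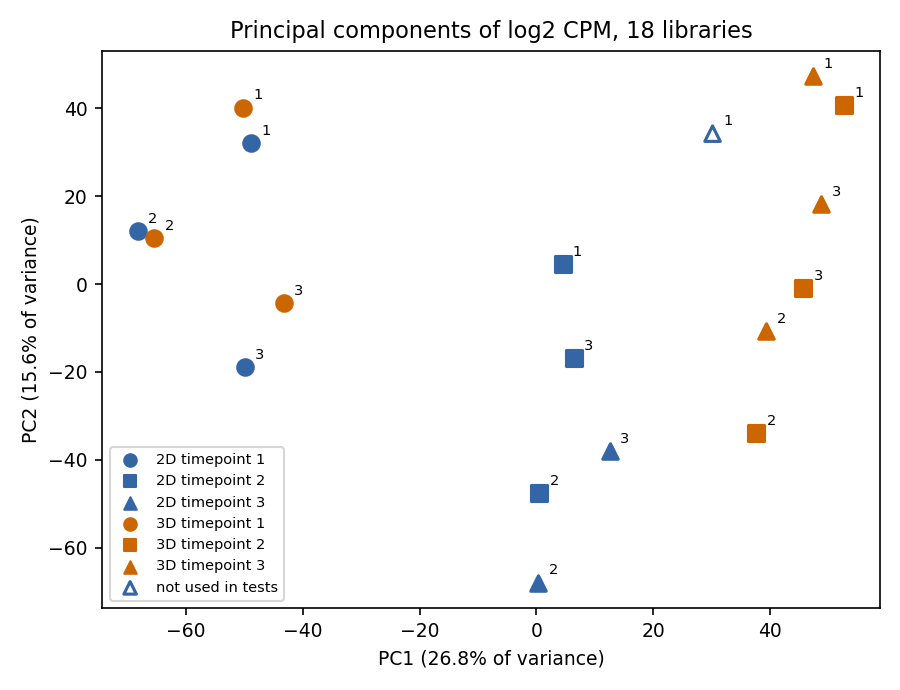
Principal components 1 and 2 of log2 CPM for the 18 libraries, with the percent of variance on each axis; colour gives the culture, shape the timepoint and the number the replicate. The 6 libraries of timepoint 1 lie on the left whichever their culture, and the open triangle, 2D timepoint 3 replicate 1, lies at 30.2 on the first axis while the other 2D libraries of that timepoint lie at 0.291 and 12.6.

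At timepoint 1 edgeR called no gene between 3D and 2D cells. Genes of the stress response and the endoplasmic reticulum were at close levels in both cultures: DDIT3, the stress transcription factor CHOP, was at 7.36 ± 0.639 CPM in 2D and 6.53 ± 1.52 CPM in 3D (SD, n = 3 each), and HSPA5, the chaperone BiP, at 168 ± 52.4 and 167 ± 62.1 CPM. The genes of the filamin and actomyosin system were likewise close, with FLNA at 2300 ± 242 CPM in 2D and 2270 ± 501 CPM in 3D. Of the 18 measured TGF-beta targets 16 lay above 0, with a median log2 fold change of 0.33 and no member called, and the list passed camera only at the preset correlation (adjusted p = 0.7 with an estimated correlation). CCN2, connective tissue growth factor, stood at 9.14 ± 3.29 CPM in 2D and 22.4 ± 9.51 CPM in 3D and did not pass the gene-wise test.

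The 0 calls at timepoint 1 come from edgeR's quasi-likelihood test of 18592 genes with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 it gave 244 genes, and 388 with the replicate block, which also made 0 calls after adjustment; DESeq2 and limma-voom made 0 calls as well. Without the filter 49 were called, 31 higher and 18 lower. Of the TGF-beta list, 1 member was higher when adjusted over the list alone. The list passed camera with an adjusted p of 4.1e-08, and had an adjusted p of 0.7 with an estimated correlation. The 25 immediate early genes had a median of 0.13 and a camera adjusted p of 0.00034 (adjusted p = 0.7 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. The 13 mitochondrially encoded genes had a median of -0.19 and a camera adjusted p of 0.00074 (adjusted p = 0.98 with an estimated correlation), with no member called. Interferon response genes, YAP-TAZ targets, and nuclear-retained and short-lived RNAs each passed camera at an adjusted p of 0.034, with medians of -0.06, 0.03 and -0.12; none had a member called, and the adjusted p was 0.38, 0.98 and 0.7 with an estimated correlation.

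At timepoint 2 the 3D cells had lower expression of ELF3 and of several junction genes than 2D cells. ELF3, an ETS factor of epithelial differentiation (ENSG00000163435, chromosome 1, 202007945 to 202016009 on hg38, protein-coding), fell by 3.68 on the log2 scale, SE 0.50, from 19 ± 4.34 CPM in 2D to 1.49 ± 0.701 CPM in 3D (SD, n = 3 each; edgeR adjusted p = 0.0105). The tight junction genes OCLN and CLDN4 fell, with log2 fold changes of -3.29 and -2.97. The kallikrein protease KLK7, which acts in the shedding of keratinised cells, fell by 4.82, from 1.95 ± 1.22 to 0.0684 ± 0.119 CPM. CKS2, a cyclin-dependent kinase subunit, rose from 9.71 ± 1.83 to 30.2 ± 10.2 CPM (log2 fold change 1.64, SE 0.23, adjusted p = 0.0113). NOX5, an NADPH oxidase, rose from 2.91 ± 0.319 to 13.4 ± 5.75 CPM (log2 fold change 2.20). The largest rise among the genes named by the rule was that of LBH, a transcriptional cofactor (chromosome 2, 30231534 to 30260028), from 0.177 ± 0.136 to 2.3 ± 1.75 CPM, with a log2 fold change of 3.68 and an SE of 0.85.

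The other named genes that rose at timepoint 2 were the noncoding RNAs LINC02777, SFTA1P and LINC00460, with log2 fold changes of 2.16, 1.86 and 1.54, the collagen prolyl hydroxylase subunit P4HA3 at 1.82, and the metallothionein pseudogene MT1L at 1.85, whose reads are uncertain because it closely resembles the other metallothioneins. Those that fell were the deubiquitinase USP2 at -2.94, the cytosolic phospholipase PLA2G4F at -2.89, the calcium channel regulator CRACR2B at -2.85, and AL691482.3 at -3.75, a noncoding gene that overlaps ELF3 and whose reads cannot be told from those of ELF3, since the strand used in counting is not given in the sources used here.

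Of the 33 measured junction and polarity genes, 8 fell at timepoint 2 and none rose; adjusted over the list alone 17 fell, and 20 fell with the replicate block. CLDN1, CLDN7 and the desmosomal DSC2 fell, with log2 fold changes of -1.80, -0.83 and -1.49. The list passed camera (adjusted p = 4.6e-12; adjusted p = 0.036 with an estimated correlation). All 30 genes of G1-S and DNA replication had a positive log2 fold change, with a median of 0.69. CDT1, E2F1 and GINS2 were called, at 0.88, 0.89 and 1.45, and 18 passed when adjusted over the list alone and 22 with the block (camera adjusted p = 1.5e-11; adjusted p = 0.44 with an estimated correlation). The 32 G2-M and mitosis genes were also all above 0, with a median of 0.63. Of these CKS2, BIRC5 and UBE2C were called, 7 passed when adjusted over the list alone and 8 with the block (camera adjusted p = 7.7e-08; adjusted p = 0.59 with an estimated correlation).

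At timepoint 2 camera also called the ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes, and none of these list calls was kept with an estimated correlation. All 40 cytosolic ribosomal protein genes had a positive log2 fold change, with a median of 0.98. None was called over all genes, 39 were higher when adjusted over the list alone and 33 with the replicate block (camera adjusted p = 1.4e-16; adjusted p = 0.44 with an estimated correlation). RPL27 was at 1610 ± 269 CPM in 2D and 3890 ± 866 CPM in 3D. The 30 nuclear oxidative phosphorylation genes had a median of 0.47, with 0 called, 5 higher when adjusted over the list alone and 9 with the block (camera adjusted p = 3.1e-05; adjusted p = 0.59 with an estimated correlation). All 13 mitochondrially encoded genes were below 0, with a median of -1.12. MT-ATP8 and MT-ND4L fell, with log2 fold changes of -1.71 and -1.45, and all 13 were lower when adjusted over the list alone and with the block (camera adjusted p = 6.3e-10; adjusted p = 0.39 with an estimated correlation). In the same libraries mitochondrial genes took 0.364% to 0.482% of the counts in 3D and 0.908% to 1.18% in 2D, and the 10 most abundant genes took 11.1% to 13.1% in 3D and 8.41% to 9.76% in 2D.

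ATF3 and STC2, both induced by the PERK-ATF4 arm of the unfolded protein response, fell, ATF3 from 26.1 ± 4.27 to 6.51 ± 1.85 CPM and STC2 with a log2 fold change of -1.32. They were the 2 members called of the 30 PERK-ATF4 targets, and 7 were lower when adjusted over the list alone and 8 with the block (camera adjusted p = 0.00022; adjusted p = 0.036 with an estimated correlation, and 0.076 with the block as well). Of 25 immediate early genes 5 fell, FOSB, ATF3, NR4A2, BTG2 and KLF4, the last named after its value was seen, while 6 were lower when adjusted over the list alone and 7 with the block (camera adjusted p = 0.027; adjusted p = 0.59 with an estimated correlation). The median of this list was -0.17 with the block. It was 0.02 with the length and GC offset as well, where the list did not pass (camera adjusted p = 0.17). DDIT3 was at 16.8 ± 0.478 CPM in 2D and 10.6 ± 1.58 CPM in 3D and passed only with the block (adjusted p = 0.0669, and 0.0136 with the block). Of the 30 genes of the translocon and N-glycosylation, SEC61B, SEC61G and OSTC rose, by 0.97, 1.10 and 0.99, while 6 passed when adjusted over the list alone and 9 with the block (camera adjusted p = 0.0084; adjusted p = 0.48 with an estimated correlation). Among the ATF6 and IRE1-XBP1 targets 1 member each rose, SDF2L1 by 0.78 and SERP1 by 0.62, and neither list passed camera (adjusted p = 0.73 and 0.82). ID1 and ID3, inhibitors of basic helix-loop-helix factors, rose by 0.92 and 1.32 in the TGF-beta list (camera adjusted p = 0.0052; adjusted p = 0.59 with an estimated correlation), in which 4 passed when adjusted over the list alone. MT2A, a metallothionein gene, rose from 3090 ± 507 to 7550 ± 1040 CPM.

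In the comparison of 3D against 2D at timepoint 2, 277 genes differed by edgeR's test, 131 higher and 146 lower in 3D, and 186 of them by a fold of at least 2. The fit with the replicate block called 2949 genes, 1674 higher and 1275 lower, among them all 277. The authors' deposited table for this timepoint lists 489 genes at an adjusted p under 0.05, 201 higher and 288 lower, and 260 of them were called here in the same direction. Without 3D replicate 1 the count was 0, without 2D replicate 2 it was 3, without 2D replicates 1 and 3 in turn 18 and 31, and without 3D replicate 3 it was 57. DESeq2 called 1336.

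**Figure D2:**
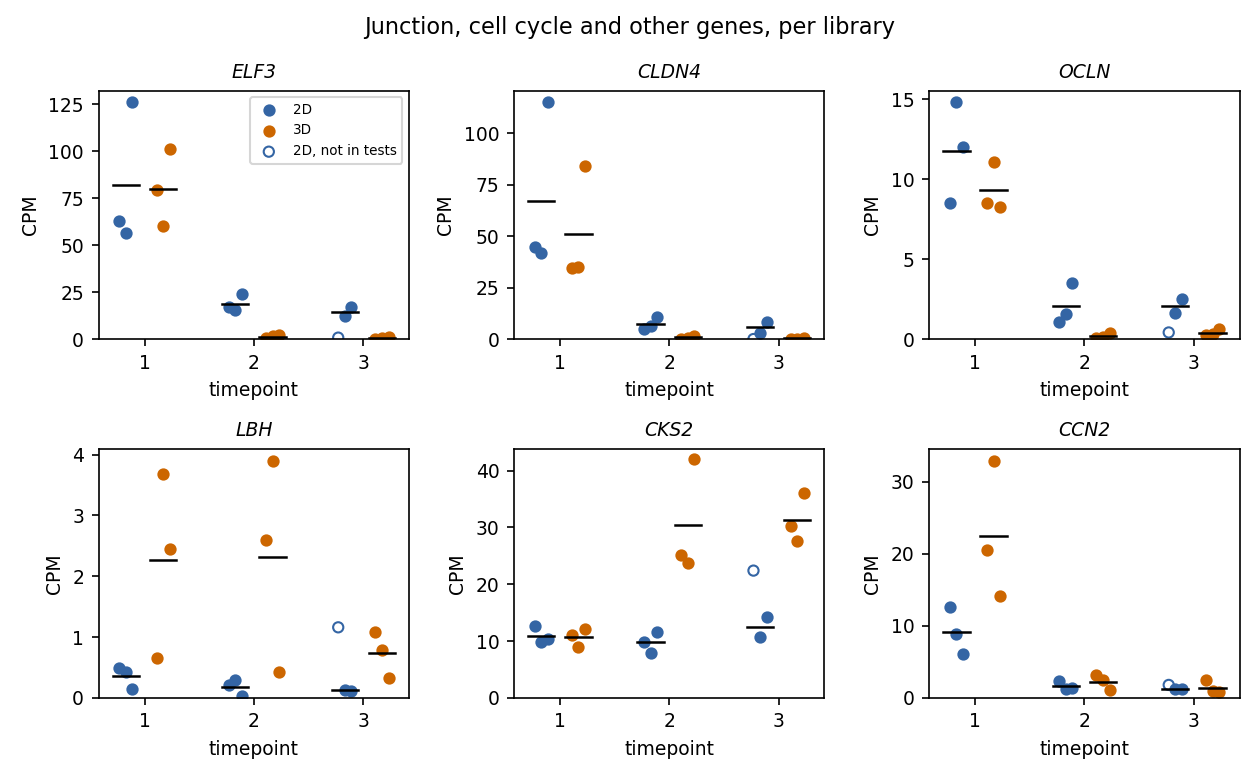
CPM of 6 genes in each library by timepoint, scaled over all 18 libraries, on linear axes from 0; bars are means of the libraries used in the tests, and the open circle is 2D timepoint 3 replicate 1. ELF3, CLDN4 and OCLN fell in both cultures after timepoint 1 and were lower in 3D than in 2D at timepoint 2, while CKS2 was higher in 3D.

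At timepoint 3 several genes of the integrated stress response were lower in 3D. ATF3 (ENSG00000162772, chromosome 1, 212613436 to 212620777) fell by 4.43 log2 units, SE 0.37, from 75.9 ± 6.08 CPM in 2D (SD, n = 2) to 3.52 ± 0.226 CPM in 3D (SD, n = 3; edgeR adjusted p = 3.79e-05). DDIT3 fell by 2.06, SE 0.20, from 36.5 ± 3.74 to 8.73 ± 0.931 CPM (adjusted p = 9.5e-05). CHAC1, which degrades glutathione and is a target of ATF4, fell by 3.85 from 9.26 ± 2.87 to 0.641 ± 0.125 CPM, and ADM2, a peptide hormone gene, fell by 4.36 from 5.16 ± 0.562 to 0.25 ± 0.028 CPM. ELF3 and KLK7, lower at timepoint 2, were lower again. ELF3 fell by 4.19 from 14.6 ± 3.43 to 0.8 ± 0.606 CPM, and KLK7 fell by 6.73.

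Of the 30 PERK-ATF4 targets 9 fell at timepoint 3 and none rose; 15 were lower when adjusted over the list alone and 16 with the block (camera adjusted p = 4.3e-15; adjusted p = 0.00032 with an estimated correlation). Besides ATF3, DDIT3 and CHAC1 they were STC2, at -2.11, PPP1R15A, the phosphatase subunit GADD34, at -2.25, and ASNS, TRIB3, SESN2 and PCK2, these 4 named after their values were seen. ATF4 itself was at 255 ± 21.7 CPM in 2D and 218 ± 23.5 CPM in 3D (adjusted p = 0.68). Of the 23 ATF6 targets and chaperones HERPUD1 alone was called and fell, by 0.72, from 130 ± 5.51 to 78.9 ± 3.82 CPM, and of the 20 IRE1-XBP1 targets none was called over all genes or adjusted over the list alone (camera adjusted p = 0.73 and 0.31). With the block 1 was higher and 1 lower in each list. HSPA5 was at 62.1 ± 4.99 CPM in 2D and 50.3 ± 11.1 CPM in 3D, and XBP1 at 112 ± 15.6 and 82.5 ± 10 CPM, which passed only with the block (adjusted p = 0.247, and 0.0214 with the block). ERN1, the gene of IRE1, was at 5.8 ± 1.48 and 2.09 ± 0.745 CPM and also passed only with the block (adjusted p = 0.12, and 0.00469 with the block).

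**Figure D3:**
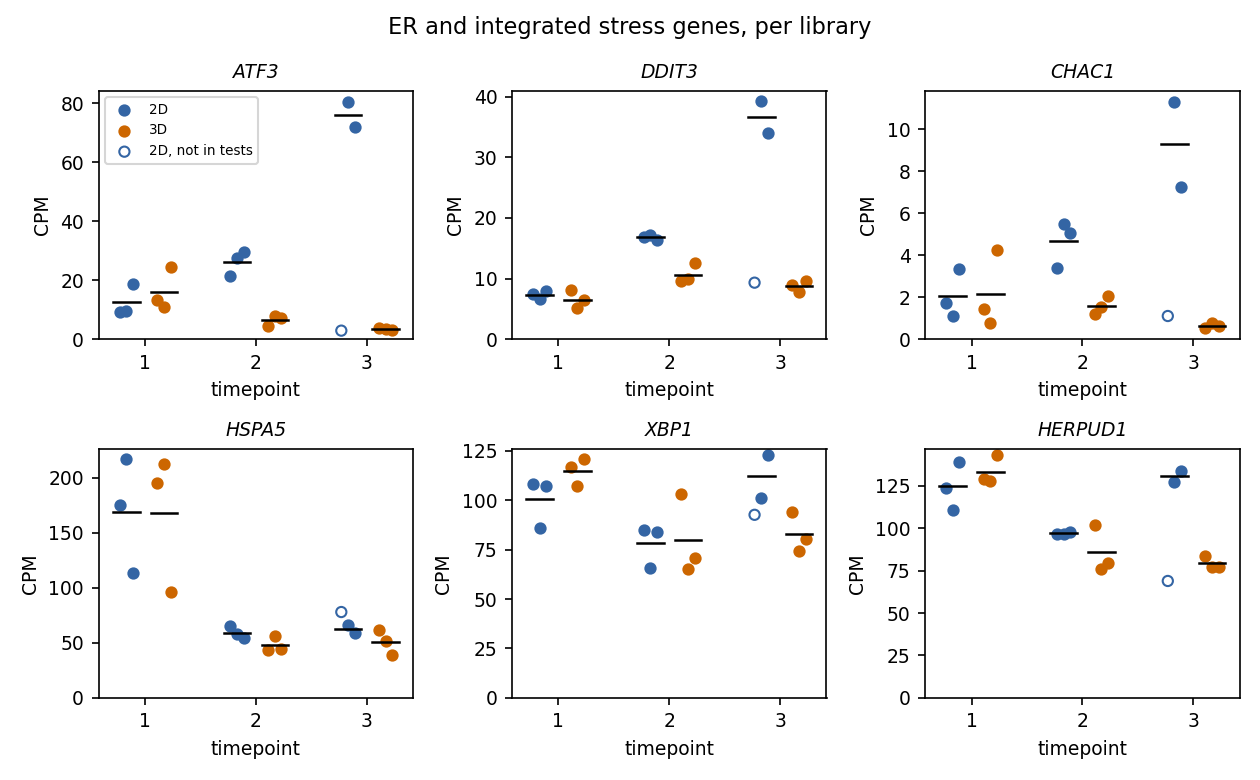
CPM of 6 genes of the unfolded protein and integrated stress responses in each library by timepoint, scaled over all 18 libraries, on linear axes from 0; bars are means of the libraries used in the tests. In the tested 2D libraries, ATF3, DDIT3 and CHAC1 are highest at timepoint 3, where 3D libraries lie far below. The open circle, 2D timepoint 3 replicate 1, lies near the 3D libraries for these genes and was not tested.

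Of 25 immediate early genes, which respond within minutes to growth factors or stress, 11 were lower in 3D at timepoint 3 and none higher; 14 were lower both when adjusted over the list alone and with the block (camera adjusted p = 5.9e-14; adjusted p = 0.04 with an estimated correlation, and 0.063 with the block as well). FOSB fell by 3.26 from 36 ± 4.58 to 3.75 ± 0.97 CPM, and KLF4 and FOS had log2 fold changes of -2.43 and -1.69. ATF3 belongs to this list as well as to the PERK-ATF4 targets. Of 22 p53 targets 4 fell, BBC3, GDF15, CDKN1A and BTG2, at -2.13, -2.45, -1.01 and -0.90, and 7 were lower when adjusted over the list alone (camera adjusted p = 0.00037; adjusted p = 0.025 with an estimated correlation). GDF15 and BBC3 are also known targets of the integrated stress response. Of 28 interferon response genes IRF7, IRF9, IRF1 and HLA-B fell, at -1.41, -1.09, -1.05 and -0.84, and the same number passed when adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.04 with an estimated correlation, and 0.063 with the block as well). SQSTM1, the autophagy receptor p62, fell by 1.36 from 1560 ± 292 to 609 ± 41.9 CPM.

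The junction list had the same direction at timepoint 3, where 5 of 33 genes fell: CLDN1, CLDN4, CLDN7 and DSC2, and OCLN, named after its value was seen. The log2 fold changes of CLDN1, CLDN4, CLDN7 and OCLN were -2.17, -3.52, -1.45 and -2.31. Of the list 15 were lower when adjusted over the list alone (camera adjusted p = 2.9e-10; adjusted p = 0.04 with an estimated correlation). Of 20 squamous differentiation genes KLK7 and SPRR1A fell, the latter with a log2 fold change of -3.35 and reads that the SPRR paralogs share to an unknown degree. Of the list 14 were lower when adjusted over the list alone and 12 with the block (camera adjusted p = 3.2e-09; adjusted p = 0.25 with an estimated correlation, and 0.0097 with the block as well). All 32 G2-M and mitosis genes were above 0, with a median of 1.08. CKS2 alone was called, at 1.33, and 26 were higher when adjusted over the list alone and 10 with the block (camera adjusted p = 2.7e-14; adjusted p = 0.34 with an estimated correlation). The 15 replication-dependent histone genes, listed as a check of poly-A selection, went the other way, with a median of -0.59 with the block. With the length and GC offset as well, 1 was higher and 5 were lower (camera adjusted p = 0.016 at the preset correlation). The 40 ribosomal protein genes had a median of 0.37 with 0 called over all genes, over the list alone or with the block (camera adjusted p = 0.0041; adjusted p = 0.84 with an estimated correlation), and the 13 mitochondrially encoded genes a median of -0.48 with 0 called (camera adjusted p = 0.013; adjusted p = 0.79 with an estimated correlation).

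Among the genes higher in 3D at timepoint 3, ZNF107, a zinc finger gene, was at 0.15 ± 0.0605 CPM in 2D and 1.9 ± 0.204 CPM in 3D. At timepoint 1 it was at 1.51 to 3.06 CPM in 2D and 0.828 to 3.1 CPM in 3D. LINC02777 and NOX5, which had risen at timepoint 2, were higher again with log2 fold changes of 3.08 and 1.93. MYOSLID, a noncoding RNA, rose from 5.17 ± 1.13 to 18.7 ± 5.4 CPM. EVI2A, CHRNA9, C10orf90 and SUCLG2-DT, the last an RNA divergent from SUCLG2, had log2 fold changes of 3.61, 2.64, 2.17 and 2.09. In 2D timepoint 3 replicate 1, which was not tested, ZNF107, LINC02777, NOX5 and MYOSLID were at 1.83, 3.09, 10.5 and 21 CPM. EVI2A, CHRNA9 and C10orf90 were at 2.35, 3.06 and 2.49 CPM in it. These levels lay within the range of the 3D libraries, while SUCLG2-DT, at 0.669 CPM, lay between the cultures. Among the lower genes the mucin MUC16, TINCR and the lymphoid surface gene CD7 had log2 fold changes of -5.37, -4.25 and -4.05. In the same untested 2D library MUC16, TINCR and CD7 were at 0.126, 0.164 and 0.278 CPM, and ELF3 and KLK7 at 0.909 and 0 CPM. These levels too lay within the range of the 3D libraries. By edgeR's test 0 of 22 YAP-TAZ targets and 0 of 32 integrin and focal adhesion genes were called at timepoint 2 or 3, over all genes or adjusted over the list alone, and neither list passed camera (adjusted p = 0.71 for both at timepoint 2, and 0.85 and 0.93 at timepoint 3). With the replicate block 2 YAP-TAZ targets were higher and 2 lower at timepoint 2 and 1 higher at timepoint 3, and of the integrin and focal adhesion genes 2 were higher and 1 lower at timepoint 2 and 1 higher and 2 lower at timepoint 3. Of 22 SRF-MRTF targets 0 were called at either timepoint, whereas with the block 5 were higher and 1 lower at timepoint 2 and 1 lower at timepoint 3. At timepoint 2 the list had a median of 0.39 and 1 member higher when adjusted over the list alone, and passed camera (adjusted p = 0.0084; adjusted p = 0.59 with an estimated correlation), and at timepoint 3 it did not (adjusted p = 0.83). The 40 actin and actomyosin genes had medians of 0.39 and 0.23 with the block at timepoints 2 and 3. With the length and GC offset as well, 20 were higher and 1 lower, then 9 higher and 1 lower (camera adjusted p = 0.00065 and 0.00076 at the preset correlation).

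The comparison of 3D against 2D at timepoint 3 called 278 genes, 43 higher and 235 lower in 3D, 237 of them by a fold of at least 2. The replicate block gave 1813, 827 higher and 986 lower, with all 278 among them. The authors' deposited table lists 294 genes for this timepoint, 36 higher and 258 lower, of which 242 were called here in the same direction. The library of 2D timepoint 3 replicate 1, not in the tests, had levels of these stress genes near those of 3D libraries: ATF3, DDIT3 and CHAC1 were at 2.95, 9.34 and 1.11 CPM. The rise in 2D is therefore that of 2 of the 3 libraries with this label. With the 18th library included the count was 0, and 1052 with the block. Without 2D replicate 2 it was 35, without 3D replicate 1 it was 71, without 3D replicate 3 it was 135 and without 2D replicate 3 it was 160. Fitted on the compared groups alone it was 183. DESeq2 called 1021.

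The lists of timepoints 2 and 3 overlapped. Of the genes higher in 3D, 17 were called at both, where 0.3 would be expected of independent lists, and of the genes lower in 3D 62 were called at both, with 1.8 expected; the comparisons share no library. No gene was called in opposite directions.

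**Figure D4:**
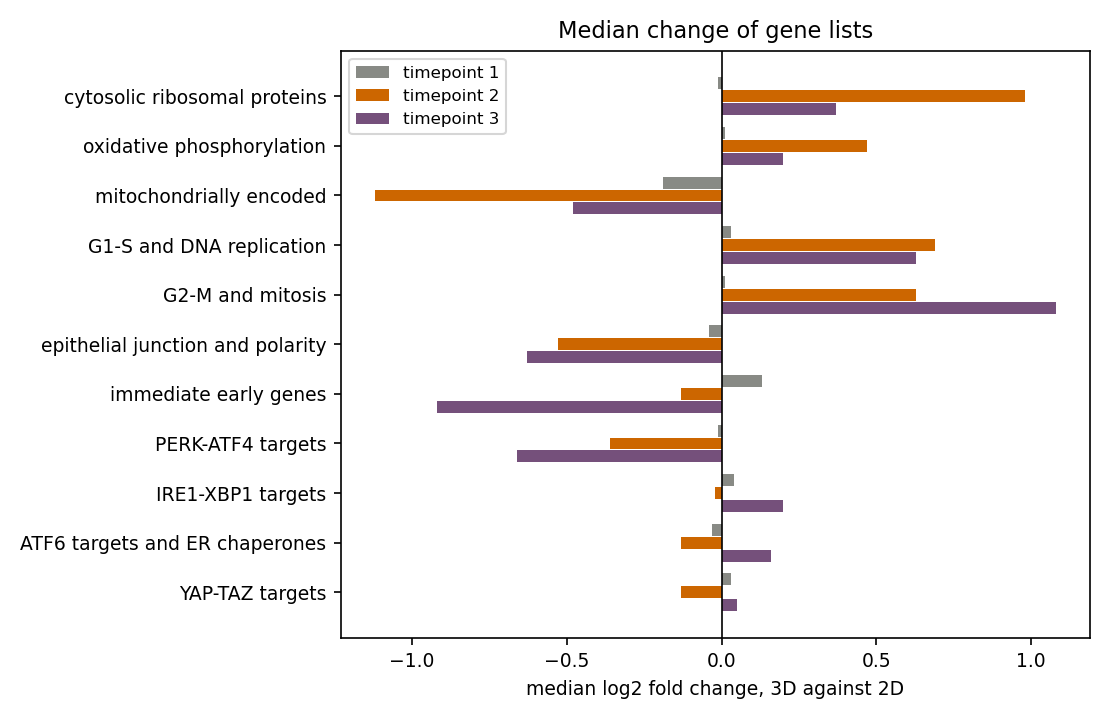
Median log2 fold change, 3D against 2D, of the measured members of 11 gene lists at timepoints 1, 2 and 3, with bars from 0. Ribosomal protein genes have their largest median at timepoint 2, at 0.98, and PERK-ATF4 targets their lowest at timepoint 3, at -0.66.

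Averaged over the 3 timepoints, 3D cells had more LBH, KANK4 and TGM2 and less MUC16, ELF3, TINCR and CLDN4. LBH had a log2 fold change of 2.97, SE 0.52, and KANK4, a regulator of actin dynamics, one of 2.26. The transglutaminase TGM2 had a log2 fold change of 1.48, and the channel genes CHRNA9 and KCNJ15 had 1.72 and 1.44. LINC02777 and NOX5 were higher by 1.96 and 1.38. ELF3 fell by 2.63 (SE 0.28, edgeR adjusted p = 0.000236). MUC16, TINCR, CLDN4, VNN3P, the phosphatase DUSP8, CRACR2B and ADM2 had log2 fold changes of -2.82, -2.32, -2.30, -2.19, -2.12, -2.11 and -1.98. The untested library of 2D timepoint 3 replicate 1 held LBH at 1.16 CPM, above every 3D library of that timepoint, and CLDN4 at 0.139 CPM, below every one. Its KANK4, TGM2 and KCNJ15, at 2.23, 14.3 and 7.03 CPM, lay within the range of those 3D libraries.

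For 3D against 2D averaged over the 3 timepoints, 955 genes passed the test, 419 higher and 536 lower. With the replicate block 3484 passed, 1783 higher and 1701 lower, so that the larger share was higher. DDIT3 fell by 0.96 on average, SE 0.11 (adjusted p = 0.000264), while HSPA5 at -0.21, XBP1 at -0.07 and ATF6 at -0.19 did not pass. Of 30 PERK-ATF4 targets 11 were lower, 12 when adjusted over the list alone (camera adjusted p = 9.1e-11; adjusted p = 0.0019 with an estimated correlation), and of 33 junction genes 11 were lower, 22 when adjusted over the list alone (camera adjusted p = 1.2e-12; adjusted p = 0.026 with an estimated correlation). Without 2D timepoint 3 replicate 2 the count was 166 and without 3D timepoint 2 replicate 2 it was 1724. With 18 libraries it was 134, and 3305 with the block.

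Within 2D culture CYP1A1, a target of the aryl hydrocarbon receptor, fell from timepoint 1 to timepoint 2, from 154 ± 32.3 to 1.4 ± 0.268 CPM (n = 3 each), and the cytokine genes CXCL10 and LIF and OR2I1P had log2 fold changes of -5.77, -4.45 and -4.26. KLK7, SPRR1B, SPRR1A and SAMSN1 rose by 5.50, 3.24, 3.23 and 3.10, and PLA2G4F went from 0.00501 ± 0.00868 CPM, a single count in 1 of 3 libraries, to 1.88 ± 0.895 CPM. Of 20 squamous differentiation genes 4 rose and none fell, the same numbers when adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.57 with an estimated correlation). Of 25 immediate early genes 14 fell and none rose, NR4A1 and EGR3 at -3.53 and -3.66, with 16 lower and 2 higher when adjusted over the list alone (camera adjusted p = 9.1e-12; adjusted p = 0.22 with an estimated correlation). Of 22 YAP-TAZ targets 8 fell, CCN1 and AMOTL2 at -2.03 and -1.19, with 11 lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.32 with an estimated correlation). HSPA5 fell by 1.51, from 168 ± 52.4 to 59 ± 5.73 CPM. From timepoint 1 to 2, 1092 genes changed in 2D, 494 up and 598 down, and 2539 with the replicate block.

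By timepoint 3 PERK-ATF4 targets had risen in the tested 2D libraries, replicates 2 and 3. The mean log2 CPM of the list was 5.88 and 5.95 in these, beside 5.10 to 5.17 in 2D at timepoint 1. In 2D timepoint 3 replicate 1, left out of the tests, it was 5.03, so the gain below is not that of all libraries with this label. DDIT3 rose by 2.31 from 7.36 ± 0.639 CPM (n = 3) to 36.5 ± 3.74 CPM (n = 2), and TRIB3, STC2 and PCK2 by 2.49, 1.92 and 1.86. In all 11 of the 30 genes rose with none falling, 11 also when adjusted over the list alone (camera adjusted p = 1.8e-08; adjusted p = 0.0042 with an estimated correlation). ATF3 rose by 2.60, whereas NR4A1, MAFF and EGR3 were lower than at timepoint 1, at -2.71, -1.61 and -3.14. GPNMB, a lysosomal glycoprotein gene, rose from 0.109 ± 0.0642 to 2.94 ± 0.596 CPM, SPRR1B rose by 3.96, and SERPINB10 fell by 5.30. Of 22 YAP-TAZ targets 9 fell and 1 rose, CCN2 and TEAD1 at -2.97 and -1.80, and 13 were lower and 2 higher when adjusted over the list alone (camera adjusted p = 1.5e-05; adjusted p = 0.39 with an estimated correlation). For timepoint 3 against timepoint 1 in 2D, 903 genes changed, 465 up and 438 down, and 1954 with the block. Without 2D timepoint 3 replicates 2 and 3 in turn, which leaves a lone library assumed to vary like the other groups, the counts were 206 and 208, and without 2D timepoint 1 replicates 1 and 2 in turn they were 527 and 531.

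In 3D junction and immediate early genes fell with time, and whether these lists changed more than in 2D was not tested. From timepoint 1 to timepoint 2, 16 of 33 junction genes fell, among them OCLN, OVOL1 and CLDN1 at -5.46, -5.08 and -4.23, with 19 lower when adjusted over the list alone (camera adjusted p = 1.5e-14; adjusted p = 0.021 with an estimated correlation). CLDN4 fell from 51.1 ± 28.3 to 0.951 ± 0.847 CPM. Of 25 immediate early genes 21 fell, FOSB and KLF6 at -3.51 and -1.69, with 22 lower when adjusted over the list alone (camera adjusted p = 3.9e-17; adjusted p = 0.021 with an estimated correlation, and 0.077 with the block as well). Of 40 ribosomal protein genes 17 rose, with 38 higher when adjusted over the list alone (camera adjusted p = 1.1e-13; adjusted p = 0.54 with an estimated correlation). INSC, an adaptor of spindle orientation, rose from 1.36 ± 0.346 to 30.7 ± 7.91 CPM, and KANK4, SCG5 and CHRNA9 rose by 5.00, 5.37 and 4.71. CYP1A1 fell by 7.76, and TPPP fell by 5.78. The lncRNA UCA1 had no count in the 3 libraries of timepoint 1 and 3.34 ± 3.36 CPM at timepoint 2.

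From timepoint 1 to timepoint 3 in 3D, 17 junction genes and 22 immediate early genes fell, with 20 and 23 lower when adjusted over each list alone (camera adjusted p = 7.1e-15 and 2.4e-23; adjusted p = 0.022 and 0.02 with an estimated correlation, and 0.0065 and 0.052 with the block as well). ATF3 and PPP1R15A fell, at -2.19 and -1.41, while TRIB3 rose by 1.15. BDKRB1, the bradykinin receptor B1 gene, rose from 0.185 ± 0.113 to 4.49 ± 0.881 CPM, and TP73 from 0.736 ± 0.262 to 7.32 ± 1.42 CPM. POU2F3 and TNNT2 went from 1.5 ± 0.974 and 1.96 ± 2.29 CPM to no count in 3 libraries, and NFATC2 from 8.61 ± 3.42 to 0.0139 ± 0.0241 CPM. Of 22 YAP-TAZ targets 11 fell and 1 rose, CCN2 at -3.97, with 12 lower and 2 higher when adjusted over the list alone (camera adjusted p = 2.4e-06; adjusted p = 0.25 with an estimated correlation).

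The comparison of timepoint 2 against timepoint 1 in 3D called 2801 genes, 1359 up and 1442 down, and that of timepoint 3 against timepoint 1 in 3D called 2049, 756 up and 1293 down. With the replicate block these were 5279 and 4447. Without 3D timepoint 1 replicate 2 they were 1256 and 1131. Of the genes that fell from timepoint 1 to 2, 464 fell in both cultures, with 46 expected of independent lists, and 272 rose in both, with 36 expected. From timepoint 1 to 3, 352 fell and 191 rose in both, with 30 and 19 expected, 6 rose in 2D and fell in 3D, and 1 fell in 2D and rose in 3D.

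Whether the difference between the cultures itself changed with time was tested as an interaction. From timepoint 1 to timepoint 3 it changed for 34 genes, and for 33 of these towards lower expression in 3D relative to 2D. ATF3 led them with an interaction log2 value of -4.79 (SE 0.48, adjusted p = 0.000457), followed by AL691482.3 at -4.71, GPNMB at -4.50, ADM2 at -4.28 and ELF3 at -4.16. A negative value need not be a fall in 3D. GPNMB was at 0.331 to 0.493 CPM in 3D at timepoint 1 and 0.301 to 0.866 CPM at timepoint 3. In 2D it went from 0.0604 to 0.182 CPM at timepoint 1 to 2.53 and 3.38 CPM in the tested libraries of timepoint 3. The untested one held 0.77 CPM. ELF3 did fall in 3D, from at least 60.1 CPM to at most 1.45 CPM. With the replicate block 290 genes passed, 100 towards higher and 190 towards lower expression in 3D relative to 2D. With the 18th library none passed, with or without the block. From timepoint 1 to timepoint 2 edgeR called 0 genes, with 1624 at an unadjusted p under 0.05; 243 passed with the block, DESeq2 called 41 and limma-voom called 0 in this culture by time interaction, timepoint 2 against timepoint 1.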

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

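The tests of explanations and the counts of splits below were set down only after the results they address were seen, whereas the interaction test, the scalings and the fit with all 18 libraries were chosen earlier. The difference between 3D and 2D changed between timepoint 1 and timepoint 3 for 34 genes by the interaction test, which brings them here as a difference between groups. The difference of ATF3 changed by -4.79 log2 units, and those of AL691482.3, GPNMB, ADM2 and ELF3 by -4.71, -4.50, -4.28 and -4.16. ATF3 and ADM2 are targets of the integrated stress response. AL691482.3 overlaps ELF3, so these are not independent.

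The library of 2D timepoint 3 replicate 1, which the tests do not use, lay nearer the 3D libraries on genes called between the cultures. On a scale from the 2D mean at 0 to the 3D mean at 1 of timepoint 3, it lay at 0.76 on genes called at timepoint 2 and at 0.91 on genes called at timepoint 3, where the 3D libraries lay from 0.95 to 1.05 and from 0.91 to 1.12. A swap with 3D timepoint 3 replicate 1 is argued against, since that library had a score of 3.81, above the lowest of the other 3D libraries of timepoint 3 at 3.60. For the shared date of replicate 1, the 2D timepoint 1 library stood 0.24 above its group, while this library stood 1.62 above its own. This argues against a date effect already present at timepoint 1. At timepoint 2 the 2D library of replicate 1 scored 1.40, beside 1.24 and 1.43. The genes of the score were called on these same libraries, so this cannot decide on a date effect at timepoint 2. In 3D replicate 1 was the highest at timepoints 2 and 3, at 4.28 and 3.81, so a date effect confined to later timepoints stays open. A 3D library under a 2D label stays open, because 0.91 lies within the 3D libraries and 0.76 below them. Ribosomal protein, oxidative phosphorylation and mitochondrially encoded genes lay on its 2D side, at mean log2 CPM of 10.20, 7.69 and 8.30. The 3D libraries of timepoint 3 lay from 10.65 to 10.94, 7.93 to 8.08 and 7.34 to 7.87. Its PERK-ATF4, junction, immediate early and cell cycle genes lay nearer the 3D libraries. No biological explanation was tested.

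Ribosomal protein and oxidative phosphorylation genes lay higher in 3D at timepoint 2 as lists, with 0 members called over all genes and an adjusted p of 0.44 and 0.59 with an estimated correlation. Gene length and GC content are argued against, with a median of 0.75 under the offset and 0.84 without it. The choice among the scalings made little difference, at 0.83 under the scaling nearest 0. TMM, RLE and upper-quartile scaling all align the bulk of the genes, so an error that they share was not tested. Their mean ranged over 1.15 among the 2D libraries of timepoint 1, more than the difference of 0.73 at timepoint 2. A range at least as large as the difference had been set down as the prediction of variation between libraries, and it was met. Replicate 3 stood high in both cultures, however, and a comparison within pairs was put in its place. Within pairs of one replicate number the differences were 0.69 to 0.81 at timepoint 2 and at most 0.10 in size at timepoint 1. This argues against variation between libraries beyond their replicate number, as far as 1 pair per number at timepoint 1 shows it. A technical difference that all 3D libraries of timepoint 2 share stays open beside the culture. For the mitochondrially encoded genes, which were lower, the medians of -1.09 with and -1.05 without the offset argue against length and GC content. The median was -1.12 under TMM and under the other scaling nearest 0, which again leaves an error shared by the scalings untested. Their range within one culture was 0.76 beside a difference of 1.11. Differences within pairs were at least 0.72 in size at timepoint 2 and up to 0.43 at timepoint 1. These leave variation between libraries open.

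PERK-ATF4 genes were lower in 3D at timepoint 3, and a median of -0.64 with the offset and -0.69 without it argues against length and GC content. With all 18 libraries 10 of the 16 members called lower with the replicate block were still called lower, but 0 of the 9 called without it, a comparison chosen after these counts were seen. The fold became smaller and the SE larger. For those 9 the median log2 fold change went from -2.06 to -1.65 and the median SE from 0.21 to 0.35. The median fold change of the whole list went from -0.66 to -0.55 (interquartile range 1.16 and 0.91). With all 18 libraries and no block 0 genes of any kind were called. The part of the adjustment over all genes in the lost calls was not separated. The choice of libraries stays open, since the other 2D libraries are in both fits and hold the fold up by design, and in the library left out ATF3, DDIT3 and CHAC1 were at 2.95, 9.34 and 1.11 CPM. The culture itself, the biological explanation that the design gives, stays open beside any difference the labels do not record.

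Splits of the libraries, with the real grouping counted among them, were tallied for the comparisons of groups of 3. With 10 splits no share under 0.05 can be reached. At timepoint 1 all 10 splits called at least the real 0 genes, as any split must, which decides nothing; the highest other called 931, or 1523 with the block. At timepoint 2 the real split alone called as many as 277, and the highest other called 0. For timepoint 2 against 1 in 2D, and for timepoints 2 and 3 against 1 in 3D, the real splits called 1092, 2801 and 2049. No other split called as many, and the highest other called 0. Of 100 splits for the average, 5 called at least 955, the real one among these 5. The highest called 4416, so chance is not excluded. The 2 other splits that parted as many pairs called 0 at most. For the interaction at timepoint 2 all 100 called at least the real 0, which again decides nothing, the highest 2755, and those that parted as many pairs called 0 at most.

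The split of timepoint 1 that called 931 genes set 2D replicates 1 and 3 and 3D replicate 3 against the others, and points to a structure of the samples. Both replicate 3 libraries stood high in ribosomal protein and oxidative phosphorylation genes, at 9.66 and 9.72, where the other 4 lay from 8.51 to 8.96.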

How the results depend on the processing

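The length and GC offset, the division by transcripts and the block with an estimated correlation for lists were chosen after seeing the data. The larger share of calls turned in some fits. At timepoint 2 it was lower in 3D, 131 higher and 146 lower, but 1674 higher and 1275 lower with the replicate block, and 559 and 198 on only the groups compared, among others. On average 419 higher and 536 lower became 1783 and 1701 with the block, and at timepoint 3, 43 higher and 235 lower became 931 and 869 with the block and the length and GC offset. For timepoint 3 against 1 in 2D, 465 up and 438 down became 175 and 302 on only the groups compared and 407 and 551 with all 18 libraries. For timepoint 2 against 1 in 3D, 1359 up and 1442 down became 2750 and 2529 with the block. With the block and the offset, 494 up and 598 down for timepoint 2 against 1 in 2D became 1715 and 1706, and 756 up and 1293 down for timepoint 3 against 1 in 3D became 2770 and 2744. Where a count below moved, the cause was not tested, except that a fold threshold leaves fewer calls by construction.

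With the replicate block the counts of 3D against 2D at timepoints 2 and 3 and on average were 2949, 1813 and 3484, and with all 18 libraries as well 2839, 1052 and 3305. With the block and counts divided by transcripts they were 3198, 1852 and 3611, and with the block and the length and GC offset 3837, 1800 and 4207. The offset alone gave 812 at timepoint 2 and 1538 on average. All 18 libraries without the block gave 82, 0 and 134. DESeq2 gave 1336, 1021 and 1977. No filter gave 49 at timepoint 1, and 1554, 1625 and 2413. Only the groups compared gave 757 and 183 at timepoints 2 and 3, and a fold of at least 2 gave 204 on average.

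For timepoints 2 and 3 against 1 in 2D, the block gave 2539 and 1954, the block with 18 libraries 2434 and 2402, with counts divided by transcripts 2726 and 2051, and with the offset 3421 and 2459. DESeq2 gave 1771 and 1587. The offset alone gave 1730 and a fold of at least 2 gave 651 at timepoint 2. No filter gave 1657 and only the groups compared 477 at timepoint 3. In 3D the block gave 5279 and 4447, with 18 libraries 5134 and 4366, with counts divided by transcripts 5488 and 4614, and with the offset 6153 and 5514. Only the groups compared gave 1023 and 1243, and a fold of at least 2 gave 1414 and 1173.

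For the interactions at timepoints 2 and 3, DESeq2 gave 41 and 146, no filter 281 and 479, the block 243 and 290, the block with 18 libraries 29 and 0, the block with counts divided by transcripts 288 and 288, and the block with the offset 575 and 315. At timepoint 2, counts divided by transcripts gave 3 and the offset 5. At timepoint 3, all 18 libraries gave 0 and only the groups compared 11.

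Leaving out 1 library gave 0 to 0 genes at timepoint 1, 0 to 218 at timepoint 2, 35 to 315 at timepoint 3 and 166 to 1724 on average. It gave 618 to 810 and 206 to 855 in 2D, 1256 to 3577 and 1131 to 2719 in 3D, and 0 to 3 and 4 to 31 for the interactions. The interaction at timepoint 3 was 4 without 2D timepoint 3 replicate 2, 8 without 3D timepoint 3 replicate 1, 9 without 2D timepoint 1 replicate 1 or 2, and 10 without 2D timepoint 3 replicate 3 or 3D timepoint 3 replicate 2. A lone library left in a group is assumed to vary like the other groups.

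Of 128 list calls, 22 passed with an estimated correlation and 16 with the block and an estimated correlation. Without replicates 1, 2 and 3 in turn camera made 112 to 136 list calls. The pairing correlation of 0.32 was 0.13 on the most variable genes.

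Of 669 calls of named genes, 669 passed with the block, 667 with DESeq2, 640 with limma-voom, 650 with RLE scaling, 653 with upper-quartile scaling, 529 on only the groups compared and 449 with all 18 libraries. Leaving out 1 library kept 3707 of 5059. Of the list calls 122 passed with the block, 119 with all 18 libraries, 125 with the offset and 76 in fry's directional test. Depth is known only through header totals of 9.31 M to 17.7 M, and genes under the filter were not tested.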

Other observations

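The test of a shared time course was set down before its result was seen, and it is the only test of an explanation in these closing parts that was. The prediction was for 3D cells further along one time course. Most genes that changed in 2D from timepoint 1 to 3 would then differ the same way between 3D and 2D at timepoint 2. That comparison shares no library with the change. Of 903 such genes 437 had the same sign, 48.4%, and 44.6% to 57% when 1 library was left out. With the replicate block the share was 51.1%. Called in both were 51 genes, 23 with the same sign and 28 with the opposite one, and with the block 500 genes, 275 with the same sign. The clear majority with the same sign that was predicted was not found. No majority, the outcome set down beforehand against the explanation, was met at 48.4%, but not at 51.1% with the block. The 2D change rests on timepoint 3 replicates 2 and 3. Replicate 1, at 0.76 towards the 3D mean on genes called at timepoint 2, was not put into this test. Genes whose change was complete by timepoint 2 also enter the share without bearing on the question. The genes called in both did differ at timepoint 2, and 28 of 51 went the opposite way. With the block 275 of 500 went the same way. These values argue against 3D cells being merely further along the course of 2D replicates 2 and 3. A course like that of replicate 1 stays open.

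The library of 2D timepoint 3 replicate 1 correlated most with 3D timepoint 3 replicate 1, at 0.987. Next came 2D timepoint 2 replicate 1, at 0.9826, above 3D timepoint 3 replicates 2 and 3, at 0.9799 and 0.9783. Both of the highest therefore share its replicate number. Among markers of other cell types, DCN was at 177 CPM over the libraries and did not differ between the cultures at timepoint 2 or 3 (adjusted p = 0.535 and 0.932), and POSTN had no count in the 2D libraries of timepoints 2 and 3 that were tested, and 1.82 ± 1.44 and 2.16 ± 1.93 CPM in 3D, which passed only with the block (adjusted p = 0.0563 and 0.111, and 0.0016 and 0.00889 with the block). SMTN was higher in 3D at timepoint 2, at 1.22 (adjusted p = 0.0163). CD14 was lower in 3D at timepoints 2 and 3, at -1.16 and -1.33.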
